A study of Rattus norvegicus with 6 samples.

How the data were processed

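RNA sequencing was done on polyadenylated RNA from 6 rat libraries, 3 per group. Groups and replicate numbers were taken from the sample titles, and table columns were matched to libraries through the column names that the sample descriptions give. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads and reverse transcribed, and libraries were size selected and amplified by PCR. The submitters' processing notes name FastQC, Trim Galore and DESeq2 without versions. The aligner, the read counter, the annotation release, the genome build and the use of strand are not given in the sources used here.

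The authors deposited 1 table of FPKM values, that is, reads or fragments scaled by gene length in kilobases and by the library total, for 20159 Ensembl gene identifiers with 1 column per library, per the labels. FPKM divides out the total but not shifts in composition between libraries, and it weights short genes strongly. The table carries no counts. Its values are, however, whole reads divided by a gene length and a library total at full numerical precision. Ratios of low values between libraries gave the relative totals, and the requirement that gene lengths be whole numbers gave the totals themselves. Each gene's length was then the smallest whole number that made its 6 values whole reads, within an absolute tolerance of 1e-09 or a relative tolerance of 1e-12. Whole reads were obtained for 20159 of 20159 genes, with a median length of 1938 bases, and they summed to between 99.29% and 99.45% of the recovered totals. In simulated data with 3796 genes, the method recovered all 6 totals and the exact reads of 99.1% of genes. The rest share a divisor among their reads and come out too small. Whether a read here is a single read or a fragment is not known. The recovered totals were 17933884, 18054266 and 17768607 for keratinocyte progenitor 1, 2 and 3, and 17678076, 18237668 and 18051522 for limbal niche 1, 2 and 3. Reads are not independent molecules, since no molecular identifiers are described, so statements from reads cover counting error only.

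The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with FPKM as deposited, a linear model with group as its only term, moderated variances with a trend on mean expression, and Benjamini-Hochberg adjustment. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, and an adjusted p under 0.05 was called. A fold change on the log2(value + 1) scale understates the change of genes with low values. The script was tested on simulated reads for the same 12085 genes with 200 changed genes. At a dispersion of 0.02 it called 43 of 50 genes changed 2-fold and 50 of 50 changed 4-fold, with 14 calls among unchanged genes. At a dispersion of 0.2 it called 3 of 50 genes changed 2-fold, 23 of 50 changed 4-fold and 45 of 50 changed 8-fold, with 10 calls among unchanged genes. The simulated reads were drawn independently with the same dispersion for all genes and no differences shared across libraries. They test the script and do not give its power in the real libraries.

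Gene names limited what could be examined. 37 gene lists (corneal, limbal, epidermal and other cell type markers, and signalling pathways such as JAK-STAT3 and PI3K-AKT) and a rule for naming genes by symbol had been fixed before the data were examined. The reference table of 47357 rat genes pairs 0 of its rows with an Ensembl identifier, so 0 of the 20159 identifiers were matched, and no list test and no gene chosen by the rule is reported. In place of the rule, at most 2 identifiers per direction are printed: in each direction the one with the lowest p among genes with a group mean of at least 10 FPKM and no overlap between groups, and the one called when limbal niche 3 was left out. Chromosomes and positions are not given for the same reason.

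Libraries were compared by Pearson correlation and principal components of log2(FPKM + 1) over the tested genes, and by a chi-square of recovered reads per pair over genes with at least 50 reads in the pair. Both groups carry replicate numbers 1 to 3. Same-numbered libraries tended to deviate from their group means in opposite directions, with correlations of -0.48, -0.35 and -0.25 between their deviations. Deviations cancel within each group, so the 3 correlations are not separate observations and are no evidence that the numbers pair libraries. The main fit has no replicate term, as fixed before the data were examined. All 10 splits of the 6 libraries into 3 and 3 were refitted. Alternatives fixed before the data were examined were other pseudocounts, filters and scalings, other variance settings of limma, library weights, a replicate block, and leaving out each library in turn. Added after seeing the data were limma-voom on the recovered reads and fits without 1 library of each group, for all 9 pairs.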

Results

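Gene expression was profiled by RNA sequencing of polyadenylated RNA in 6 rat libraries, 3 labelled as primary keratinocyte progenitors and 3 labelled as limbal niche. Keratinocyte progenitors are the dividing epithelial cells of the epidermis. The limbal niche is the cellular surrounding of the epithelial stem cells at the rim of the cornea. The study's title concerns the conversion of keratinocyte progenitors to corneal epithelial cells under the influence of limbal niche cells, and its design describes a 14-day induction phase under 3 culture conditions, of which 2 contain medium conditioned by limbal niche cells. The labels give epidermis as the tissue of all 6 libraries and do not say which culture condition a library came from. The second group is therefore called limbal niche here, as labelled, without a statement that it is the niche cells themselves or keratinocytes exposed to their medium.

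The libraries were similar in depth and in the number of genes detected. Total reads, recovered from the deposited FPKM values, ranged from 17678076 in limbal niche 1 to 18237668 in limbal niche 2. Between 16882 and 17236 of the 20159 genes had a value above 0, and between 6111 and 6642 genes reached 10 FPKM. At these depths 1 read on a gene with 2000 bases of exon corresponds to 0.0274 to 0.0283 FPKM. The 50 most abundant genes took 26.0%, 24.1% and 24.2% of the summed FPKM in keratinocyte progenitors 1, 2 and 3. The same genes took 21.6%, 26.5% and 23.6% in limbal niche 1, 2 and 3. The deposited table identifies genes by Ensembl identifier alone, and none of the identifiers was paired with a gene symbol here, so values are given by identifier, and marker genes of corneal, limbal and epidermal cells were not examined.

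The comparison that the labels imply is limbal niche against keratinocyte progenitors. No gene passed the test of a difference between the 2 groups. Of 12085 genes with a mean of at least 1 FPKM, 0 were higher and 0 were lower in limbal niche (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group), and the lowest adjusted p was 0.786. At an unadjusted p under 0.05 there were 707 genes, 284 higher and 423 lower in limbal niche, where 604 would be reached by chance among 12085 independent tests. This count lay on either side of 604 depending on the fit: it was 672 with limma-voom on the recovered reads, which also called 0 genes, 328 with a replicate block, 182 and 205 without keratinocyte progenitor 3 or 2, 1884 without keratinocyte progenitor 1 and 3693 with library weights. The direction of these genes depended on scaling, with 221 higher and 492 lower of 713 when libraries were rescaled without the most abundant genes, and 340 higher and 343 lower of 683 with median-of-ratios scaling. With keratinocyte progenitor 1 and limbal niche 1 both left out, 1804 genes passed, 867 higher and 937 lower in limbal niche 2 and 3 than in keratinocyte progenitor 2 and 3. Leaving out each of the 8 other pairs of 1 library per group called 0 genes. The pair was left out after the data were seen because these libraries did not group by label, and the 2 keratinocyte progenitor libraries that remain are nearly alike, so this choice favours a high count, which is no measure of a difference between the groups. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures beyond calling them biological replicates.

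Fold changes between the group means were mostly small. The median log2 fold change was -0.06 on the log2(FPKM + 1) scale. An absolute change of at least 1 was reached by 325 genes, 186 of them higher and 139 lower in limbal niche, and none of these passed the test. The 3 values of each group did not overlap for 1437 genes, or 11.9% of those tested, of which 560 were higher and 877 lower in limbal niche. Under the other scalings these were 428 and 1012 (rescaled without the most abundant genes) to 695 and 739 (median-of-ratios). For genes without tied values the average over the 10 splits of 3 libraries against 3 is 10% whatever the data, so it is no measure of chance. The count depends on the nearly alike keratinocyte progenitor 2 and 3. Splits that divide this pair gave 277 to 620 such genes, and the other splits that keep it together gave 903, 1935 and 4858.

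The width of the intervals sets what these libraries could show. The median half-width of the 95% confidence interval of a log2 fold change was 0.60, or 1.51-fold in FPKM + 1. For 7572 genes, 62.7% of those tested, the whole interval lay within 1 unit of log2(FPKM + 1) in either direction, which for genes with low values spans more than a 2-fold change of expression. This share was 57.3% among 5449 genes with a mean of 1 to 10 FPKM, 68.2% among 5773 genes at 10 to 100 FPKM and 59.2% among 863 genes at 100 FPKM or more. The median half-width in the same classes was 0.65, 0.55 and 0.60. For the remaining 4513 genes the interval reached or lay beyond 1 unit. When known folds were multiplied into the limbal niche values of 200 randomly drawn genes of the deposited table, limma called 2 of 50 genes changed 2-fold, 24 of 50 changed 4-fold, 40 of 50 changed 8-fold and 41 of 50 changed 16-fold. The 200 genes were changed together, and 6 genes that had not been altered were called with them, so these shares do not apply to a change in a few genes, for which the adjusted threshold is stricter.

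Among genes with a mean of at least 10 FPKM in either group and no overlap between groups, ENSRNOG00000004659 had the lowest unadjusted p of those higher in limbal niche. Its level was 23.3 ± 0.524 FPKM in keratinocyte progenitors and 58.6 ± 9.998 FPKM in limbal niche (SD, n = 3 each). The log2 fold change was 1.28 with a 95% interval from 0.86 to 1.70 (limma adjusted p = 0.793). ENSRNOG00000053250 had the lowest p of those lower in limbal niche, at 12.2 ± 3.22 FPKM in keratinocyte progenitors and 1.19 ± 0.694 FPKM in limbal niche (SD, n = 3 each). Its log2 fold change was -2.62 with a 95% interval from -3.34 to -1.90 (limma adjusted p = 0.786). The direction was the same in all 3 limbal niche libraries against all 3 keratinocyte progenitor libraries for both genes, which their choice from genes without overlap required. Both identifiers were chosen after their values were seen. With keratinocyte progenitor 1 and limbal niche 1 both left out, the limma adjusted p was 0.0141 for ENSRNOG00000004659 and 0.0165 for ENSRNOG00000053250. That fit, chosen after the data were seen, called 1804 of 12085 genes. Both identifiers had been picked on values that include the same libraries, so these p values are no support for either gene.

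2 further genes were called only when limbal niche 3 was left out. ENSRNOG00000060048 was at 0 FPKM in each keratinocyte progenitor library, at 38.2 and 35.6 FPKM in limbal niche 1 and 2, and at 0.0487 FPKM, or 2 reads, in limbal niche 3. ENSRNOG00000051257 was at 56.3, 88.3 and 88.8 FPKM in keratinocyte progenitor 1, 2 and 3, at 0.859 and 0.555 FPKM in limbal niche 1 and 2, and at 58.9 FPKM in limbal niche 3. With all 6 libraries both had a limma adjusted p = 0.793. Without limbal niche 3 the limma adjusted p was 0.00742 for the former and 0.019 for the latter. For both genes the limbal niche replicates thus differed among themselves as widely as the groups did.

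**Figure D1:**
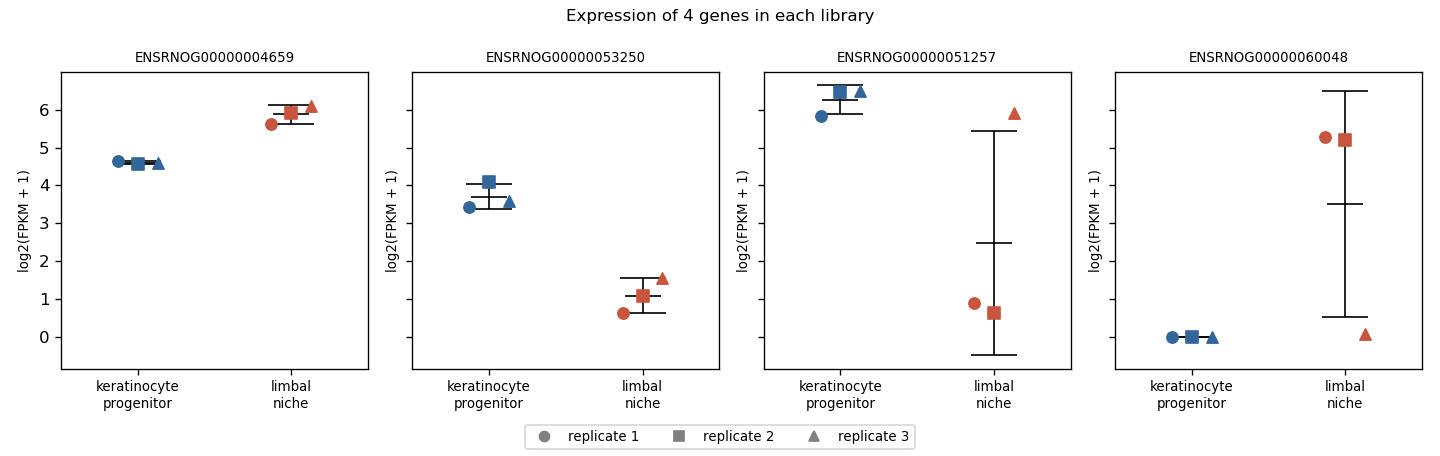
Expression of 4 genes, as log2(FPKM + 1) on a common vertical axis, in the 3 keratinocyte progenitor and 3 limbal niche libraries. Each symbol is 1 library (circle, square and triangle for replicates 1, 2 and 3), the middle bar is the group mean and the outer bars are 1 SD to either side. ENSRNOG00000004659 and ENSRNOG00000053250 do not overlap between groups, while limbal niche 3 lies among the keratinocyte progenitors for ENSRNOG00000051257. For ENSRNOG00000060048 limbal niche 3 lies beside the keratinocyte progenitors, and the groups fail to overlap only through its 2 reads.

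The libraries did not group by their labels. Over the 12085 genes, the mean Pearson correlation of log2(FPKM + 1) was 0.929 between libraries of the same group and 0.930 between libraries of different groups. The mean within groups was raised by keratinocyte progenitor 2 and 3, at 0.995. The other pairs within groups ran from 0.883 to 0.958, and pairs between groups from 0.886 to 0.968. These correlations are across genes within library pairs, and genes are not independent replicates. The difference, within minus between, was -0.0014, and 2 of the other splits of the 6 libraries into 3 and 3 gave a higher one (exact permutation over 10 splits, one-sided p = 0.3, where the smallest possible p is 0.1). All splits that divide keratinocyte progenitor 2 and 3, the most alike pair, lay lower, at -0.0105 to -0.0044. The rank of the labelled split therefore partly reflects that pair.

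Keratinocyte progenitor 1 was closer to limbal niche 2 and 3 than to its own group. Its correlation was 0.962 with limbal niche 2 and 0.968 with limbal niche 3, against 0.927 and 0.923 with keratinocyte progenitor 2 and 3. Limbal niche 1 correlated at 0.925 and 0.931 with keratinocyte progenitor 2 and 3, against 0.887 and 0.883 with limbal niche 2 and 3. The number of genes at least 2-fold apart on the log2(FPKM + 1) scale was 649 and 517 between keratinocyte progenitor 1 and limbal niche 2 and 3, and 1458 and 1538 between it and keratinocyte progenitor 2 and 3. For limbal niche 1 it was 1459 and 1303 against keratinocyte progenitor 2 and 3, and 2176 and 2138 against limbal niche 2 and 3. The first principal component, with 51.9% of the variance, placed keratinocyte progenitor 1 (-35.0) beside limbal niche 2 (-41.7) and limbal niche 3 (-30.9), and opposite keratinocyte progenitor 2 (27.1), keratinocyte progenitor 3 (31.9) and limbal niche 1 (48.6). The second component, with 26.3% of the variance, followed the labels in part. Its scores were -2.7, 28.6 and 27.0 for keratinocyte progenitor 1, 2 and 3, and -44.9, -19.2 and 11.2 for limbal niche 1, 2 and 3. Limbal niche 3 thus lay above keratinocyte progenitor 1. The labels give no sequencing or library batch, so a comparison within batches could not be made.

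Keratinocyte progenitor 2 and 3 were closer to each other than any other pair, with a correlation of 0.995 and 56 genes at least 2-fold apart. The chi-square of their recovered reads over 11356 genes with at least 50 reads had a mean of 4.46 per gene and a median of 0.895, where sampling alone gives 1 and 0.455. In the other pairs the mean ranged from 81.5 to 355 and the median from 8.34 to 31.6. The chi-square exceeded the 95th percentile of sampling for 19.5% of these genes, against 63.8% to 80.4% in the other pairs. Library preparation also adds to sampling noise, so these values do not show whether the 2 libraries came from separate cultures, and they were counted as 2 samples because the labels list them so. With keratinocyte progenitor 2 or 3 left out, 205 or 182 genes were at an unadjusted p under 0.05, against 707, and the lowest adjusted p was 1 in both fits, against 0.786.

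**Figure D2:**
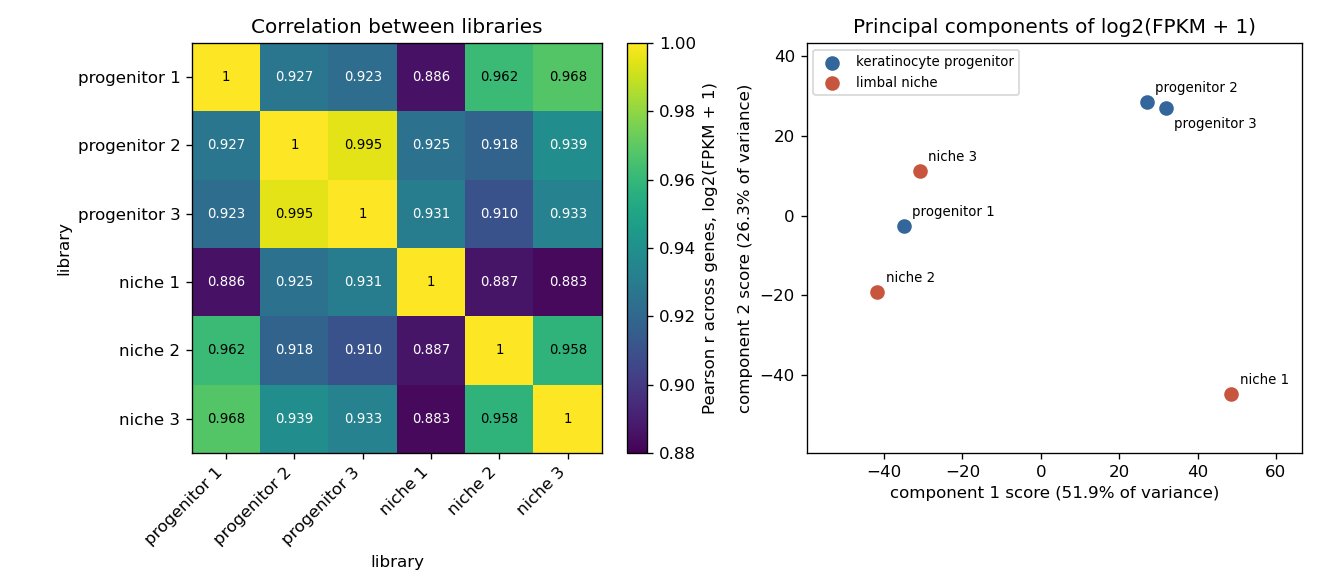
Similarity of the 6 libraries over 12085 genes. The left panel gives the Pearson correlation of log2(FPKM + 1) for each pair of libraries as a number and a colour, and the right panel gives the first and second principal component scores, coloured by labelled group. Keratinocyte progenitor 1 lies with limbal niche 2 and 3, and limbal niche 1 lies apart from all others.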

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

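With all 6 libraries, the count of called genes was 0 in the main analysis and under pseudocounts of 0.1 and 0.5, filters at 0.1 and 5 FPKM, the 4 other scalings, the 2 other variance settings, library weights, the additional requirement of a log2 fold change of at least 1, the replicate block, and limma-voom on recovered reads, the last chosen after seeing the data. The lowest adjusted p was just above the threshold with library weights, at 0.0504, against 0.786 in the main analysis and 0.988 with the replicate block. Without a filter on low values the count was 11, with a lowest adjusted p of 0.0231, none with an absolute log2 fold change of 1; the cause was not tested. Leaving out 1 library in turn gave 0 to 2 called genes, the 2 when limbal niche 3 was left out. Leaving out keratinocyte progenitor 1 and limbal niche 1 together, also chosen after seeing the data, gave 1804, and each of the 8 other pairs of 1 library per group gave 0, with 110 (keratinocyte progenitor 2 and limbal niche 2) to 2230 (keratinocyte progenitor 1 and limbal niche 3) at an unadjusted p under 0.05. The count at an unadjusted p under 0.05 was 707 in the main analysis, 328 with the replicate block, 3693 with library weights, and 4479 without both libraries numbered 1. The library weights were 0.20 for keratinocyte progenitor 1 and 0.21 for limbal niche 1. They were 0.48 and 0.72 for limbal niche 2 and 3, and 8.90 and 7.48 for keratinocyte progenitor 2 and 3. The weighted fit thus leaned mostly on the 2 libraries that are nearly alike. Leaving out 1 library in turn, the count at an unadjusted p under 0.05 ran from 182 (without keratinocyte progenitor 3) to 1884 (without keratinocyte progenitor 1). It was 1309 without limbal niche 1, 424 without limbal niche 2 and 205 without keratinocyte progenitor 2. The share of these genes that were higher in limbal niche was 284 of 707, 340 of 683 with median-of-ratios scaling and 221 of 713 when rescaled without the most abundant genes. For the 4 printed identifiers, 80 of 84 alternative values kept their direction and their side of the threshold, 4 passed it and 0 reversed: ENSRNOG00000004659 and ENSRNOG00000053250 passed without both libraries numbered 1, and ENSRNOG00000051257 and ENSRNOG00000060048 without limbal niche 3. The list tests and list means planned before the data were examined were not run, since no identifier had a symbol. Depth was close to equal in the 6 libraries; the cause of the 0 calls was not tested.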

Other observations

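The tests of all-or-none genes, of other splits of the libraries and of the left-out libraries were chosen after the results were seen; the gene length and quantile normalization tests were set before their own results were seen, though after the correlations between libraries.

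Most of the expression difference in these data runs across the labelled groups. Of the 10 splits of the 6 libraries into 3 and 3, the labelled one called 0 genes, as did 8 of the 9 others. A count of 0 is met by all 10 splits whatever the data, so it decides nothing about chance. The highest other count was 1366, for keratinocyte progenitor 1 with limbal niche 2 and 3 against keratinocyte progenitor 2 and 3 with limbal niche 1. At an unadjusted p under 0.05 the labelled split had 707 genes, 3 of the 10 splits had at least as many, and the highest other had 3871. With 10 splits no share under 0.05 can be reached. The split with 1366 is the highest of 10 and is the grouping that the correlations had already shown. It also keeps the nearly alike keratinocyte progenitor 2 and 3 on 1 side, which favours a high count. Of the splits that keep this pair together, the labelled one had 707 genes at an unadjusted p under 0.05, and the others 318, 1164 and 3871. Splits that divide the pair had 52 to 188. The count of 1366 therefore restates the correlations and is no separate evidence of a structure that the labels do not describe.

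A candidate explanation is that the labels of keratinocyte progenitor 1 and limbal niche 1 were exchanged. It was examined on the 1804 genes called between keratinocyte progenitor 2 and 3 and limbal niche 2 and 3. These genes were chosen without the 2 libraries, but the correlations had already placed both, so the shares largely restate the correlations and do not decide for the exchange. Keratinocyte progenitor 1 lay nearer to limbal niche 2 and 3 for 86.9% of them and limbal niche 1 nearer to keratinocyte progenitor 2 and 3 for 64.2%. Both held for 994 genes (55.1%), neither for 72 (3.99%) and only 1 of the 2 for 738 (40.9%). On a scale from 0 (mean of keratinocyte progenitor 2 and 3) to 1 (mean of limbal niche 2 and 3), the median position was 0.89 for keratinocyte progenitor 1 (quartiles 0.66 and 1.09) and 0.32 for limbal niche 1 (quartiles -0.14 and 0.61), so limbal niche 1 lay between the groups for many of these genes. The 72 genes that ran as labelled in both libraries include 2 of the printed identifiers. ENSRNOG00000004659 was at 23.9 FPKM in keratinocyte progenitor 1 and 48.2 FPKM in limbal niche 1, against 22.9 and 23.2 FPKM in keratinocyte progenitor 2 and 3 and 59.5 and 68.1 FPKM in limbal niche 2 and 3. ENSRNOG00000053250 was at 9.85 FPKM and 0.538 FPKM, against 15.9 and 10.96 FPKM and 1.11 and 1.92 FPKM. These 2 were chosen because the labelled groups do not overlap and are already counted in the shares, so they add nothing to them. The split still called 1474 genes after a trend on gene length was removed from each library and 1441 after quantile normalization, against 1366. The count did not fall after either step, which argues against a smooth gene length trend or unequal library composition as its whole cause. Such steps can also raise a count by removing variance, so it does not measure how much either contributed. Summed FPKM nevertheless separated this split. It was 604548, 661709 and 588024 in keratinocyte progenitor 1 and limbal niche 2 and 3. In keratinocyte progenitor 2 and 3 and limbal niche 1 it was 556097, 556778 and 540446. A higher sum means that more of a library's reads fell on shorter genes, so the split carries a difference related to gene length. Neither trend removal nor quantile normalization removes a technical difference that varies from gene to gene, and such a difference was not tested. An unrecorded batch or culture day that joined the same 3 libraries, or cultures that differed within a group, could give a similar grouping. These cannot be told apart from an exchange, as the labels name neither. An exchange alone leaves the distance of limbal niche 1 unexplained. It correlated at 0.925 and 0.931 with keratinocyte progenitor 2 and 3, which were at 0.995 with each other.

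Limbal niche 1 stood apart in a second way. It was at least 2-fold above all 5 other libraries for 343 genes and at least 2-fold below them for 215, on the log2(FPKM + 1) scale. The next highest numbers were 97 genes above, in limbal niche 2, and 23 below, also in limbal niche 2. A library with a close neighbour has few such genes by construction, so these counts do not rank the libraries beyond that. The total of 17678076 reads in limbal niche 1 was the lowest, by a small margin. Whether these genes mark another cell type was not tested, since no symbols were at hand.

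A few genes were all or none. With at least 100 reads as on and at most 5 as off, 9 genes were on in some libraries and off in all others. Of these, 4 were on in limbal niche 1 and 2 alone, with 128 to 1533 reads, against 0 reads in each keratinocyte progenitor library and at most 2 in limbal niche 3; no other pair of libraries alone shared such a gene. Of the remaining 5, 1 was on in keratinocyte progenitor 1 and limbal niche 2 and 3 alone, the split described above, 2 were on in limbal niche 1 alone, 1 in keratinocyte progenitor 1 alone, and 1 was off in keratinocyte progenitor 1 alone. ENSRNOG00000060048 is 1 of the 4, with 1533 and 1476 reads. ENSRNOG00000051257 ran the other way, with 15 and 10 reads in limbal niche 1 and 2 and 998 to 1575 in the others. Source animals of different sex or genotype could give such a pattern, with limbal niche 1 and 2 from 1 kind of animal and the other 4 libraries from another. The 4 genes cannot decide this, because their chromosomes are not known here, and sex was not tested. An exchange of keratinocyte progenitor 1 with limbal niche 1 would leave this pattern divided within both groups.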
